A study of Danio rerio with 4 samples.

How the data were processed

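Zebrafish skeletal muscle was profiled by translating ribosome affinity purification (TRAP), in which tagged ribosomes of a chosen cell type are pulled down and the RNA bound to them is extracted. Per the labels, RNA was taken at 21, 24, 27 and 34 hpf (hours after fertilization), amplified, labelled with Cy5 and hybridized on 2-colour Agilent arrays. The Cy3 channel of each array held RNA of whole larvae at 4 days post fertilization (dpf), a common reference. There was 1 array per time point, no replicate and no dye swap. The 4 arrays lay on 1 slide and their positions followed the order of time.

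The authors deposited scanner files with the intensity of each spot and of its local background in both channels, on a linear scale, per the file headers from Agilent Feature Extraction 10.10.1.1. The same files hold processed intensity values, from which the software had subtracted the background and which it had scaled between the dyes of an array. The authors also deposited a table of processed Cy5 intensity, not scaled between arrays; all 43803 spots compared at 21, 24 and 27 hpf and all 38289 intact spots at 34 hpf matched the scanner files within 0.6%. This table has 8 further columns, by their headers of whole larvae or log ratios, that could not be mapped to samples and were not used. Probe positions refer to the Zv9 (danRer7) assembly per the file headers. The deposited scanner file of 34 hpf was damaged from spot 39301 on, and for this file the unit is other than a clean intensity in its damaged rows. The 5514 non-control spots of the damaged part were left out on all arrays, and 38289 were kept.

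Probe names were brought to current symbols through the accession of the probe for 25724 probes, a listed accession for 2091, the symbol for 3798 and a synonym for 1073. The name in the file was kept for 10917 probes. Some old symbols have since passed to another gene, so values belong to the probe's transcript, under its current symbol.

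Intensities were background corrected with the normexp method (offset 50) and the log2 ratio of Cy5 to Cy3 was normalized by loess within each array, with limma 3.58.1 in R 4.3.3. Spots of the same probe were averaged, and each gene was represented by its probe with the highest mean intensity. Features entered the tests where the probe was well above background in at least 2 of the 8 array-channel measurements, which left 20242 features. Among 7969 genes with several probes, 5 had probes that moved 2-fold or more in opposite directions between 21 and 34 hpf, and 19 had probes 2-fold or more on opposite sides of the reference.

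A limma model with an intercept and centred time was fitted to the 4 log2 ratios of each feature. The intercept is the mean over the 4 time points against the reference, called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 ratio of at least 1 in size. The slope is the linear trend over time, called at an adjusted p under 0.05. With 1 array per time point, scatter around the straight line was the only measure of spread, with 2 residual degrees of freedom and 5.76 prior degrees of freedom from all features. The number of arrays limits the precision, and a gene that peaks at 24 or 27 hpf is poorly served by a straight line. All limma tests were two-sided, and values after the sign ± are standard errors of this fit.

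Differences between time points had no test. They were counted at 2-fold or more over features with Cy5 well above background on at least 1 of the arrays compared. The same count in the Cy3 channel, scaled between arrays, gave the technical level of the steps that both channels share. It leaves out the purification and amplification of the TRAP RNA. Where all probes of a gene were at background at the start or the end, the change is given as a bound. The bound uses the lowest value among probes well above background on that array, or the probe's own value where higher. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9 were used for lists and plots.

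Fixed before the data were examined were the tests and thresholds, 15 gene lists, 16 lists of cell type markers and the rule for named genes. The gene lists were fast muscle sarcomere, slow muscle, myogenic and somite regulators, presomitic mesoderm and segmentation, myoblast fusion and adhesion, excitation-contraction coupling and neuromuscular junction, sarcomere chaperones and dystrophin complex, muscle energy metabolism and glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, translation factors, proteasome, cell cycle and DNA replication, mitochondrial and cytosolic stress response, and extracellular matrix and tendon. The marker lists covered neuron, neural progenitor, eye and lens, liver, pancreas, intestine, erythrocyte, leukocyte, endothelium, epidermis and periderm, hatching gland, notochord, cartilage and bone, heart, pigment cell and neural crest, and kidney. The median of each list was set against 10000 random lists of the same size matched on expression in 20 bins.

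The rule for named genes took, among genes with an informative symbol, the 12 highest and the 12 lowest over the reference among called genes well above background in both channels on all 4 arrays. For time it took the 12 largest rises and falls from 21 to 34 hpf with the same sign in processed ratios and in Cy5 alone, the 5 largest of each successive interval, the 5 largest bounds in each direction and the 10 smallest adjusted p of the trend. For each list it took the 4 members with the largest mean ratio in size and the 4 with the largest change. A fixed panel of muscle, tissue and control genes was added. Among the genes the rule took, 1 is not reported here.

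Alternatives fixed in advance were the processed signals, median centring without loess, Cy5 alone with quantile scaling, quantile scaling of average intensity, no filter, a filter on both channels and all arrays, the mean of all probes, the deposited table, each time point left out in turn, fold thresholds of 1.5 and 3, no size threshold, and a count without a test. Chosen after seeing the data were the processed signals under the filter on both channels, an intensity trend of the spread in limma, and lists without members that a name pattern or old symbol had drawn in from another kind of gene.

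The fit was tested on simulated data with 200 planted changes. The trend test recovered 8.96% of planted changes of 1 log2 unit, 89.6% of 2 units and 100% of 4 units, with 5 of 20042 unplanted features called. The test against the reference recovered 41.8%, 100% and 100%, with 0 of 20042 unplanted features called. A planted ratio of 1 lay exactly at the size threshold, so many of these had to fail. Unplanted features had no effect of the kind tested. In the data, limma gave 15655 features an unadjusted p under 0.05 against the reference and 4555 for the trend. The adjusted threshold was thus stricter in the simulation, and these shares do not give the power in the data. The simulated noise was independent between features and arrays, so a bias shared by many features of 1 array was not covered.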

Results

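The data were 4 two-colour arrays of ribosome-bound RNA from zebrafish skeletal muscle, 1 each at 21, 24, 27 and 34 hpf, set against RNA of whole larvae at 4 dpf. Between 62.5% and 67.8% of spots were well above background in the Cy5 (TRAP) channel and between 82.1% and 83.7% in the Cy3 (reference) channel. The reference channels of any 2 arrays correlated across features at Pearson r from 0.9988 to 0.9992, and the TRAP channels of 21 and 34 hpf at 0.960. Features are not independent replicates. The median log2 ratio over all features lay between -0.11 and -0.07, and with the processed signals of the scanner software between -0.30 and -0.21. Ratios and calls are given without subtracting these medians.

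The mean over the 4 time points asked which transcripts were richer in the ribosome-bound RNA than in the older whole larvae. Genes of hatching, blood, early mesoderm and cell division led. The hatching gland cathepsin ctslb (NM_131198; probe on chromosome 12 of Zv9, 17684260 to 17684319) stood at log2 6.74 ± 0.11 and the hatching enzyme he1.2 at 6.06 ± 0.12. The embryonic globin hbbe3 had 5.95 ± 0.10, and the presomitic transcription factor msgn1 had 5.58 ± 0.12. The notochord sheath gene cmn was at 5.52, the mitotic cyclin ccnb1 at 5.50, the ribonucleotide reductase gene rrm2l at 5.34, the histone gene hist1h2a11 at 5.42 and the histone methyltransferase gene kmt5ab at 5.18. The troponin T gene tnnt2c, at 5.20 ± 0.15, was the muscle gene in this group, which also held ano9a at 5.45 and MGC174155 at 6.34.

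Transcripts of organs that mature later stood at the other end. The cone transducin gnat2 (NM_131869; chromosome 8, 26078561 to 26078620) had log2 -7.39 ± 0.13, the cone arrestin arr3a -6.52, and the lens crystallins crygm2a, crygm2d16 and crygmx -6.75, -6.27 and -6.25. The cytochrome P450 gene cyp3a65 had -7.24, the elastase gene cela1.6 -6.75, the acute phase gene crp -6.31 and the bile acid binding fabp6 -6.29. The muscle AMP deaminase ampd1 was at -6.39 ± 0.12 and hsc70 at -6.68 ± 0.25. By limma, 2569 features were higher and 3389 lower than the reference by 2-fold or more, of 20242 tested. Of these 5958 calls, 5912 had the same sign on all 4 arrays. The dyes were not swapped and the reference differs in age and tissue at once, so a ratio does not separate muscle from stage. The share of calls above the reference was 43.1%, with 37.4% under the processed signals (4219 higher, 7055 lower) and 24.0% under median centring (1627 higher, 5141 lower). With the processed signals of the 13485 features well above background in both channels on all arrays, 3657 were higher and 2962 lower, so the majority turned over. This filter leaves out features at background in Cy5, and with the main ratios it gave 2426 higher and 2538 lower. The turnover thus cannot be told apart from the choice of features.

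Cell division genes were the list that stood highest over the reference. All but 1 of the 52 measured members of cell cycle and DNA replication, 51 in number, were above it, at a median of log2 4.01, and none was below. The cyclin ccna2 had 5.04 ± 0.07, the cytokinesis kinesin kif23 4.79 and the replication clamp pcna 4.29. Fast muscle sarcomere genes lay at a median of -2.72, with 2 of 33 above and 25 below: myhz2, a fast myosin heavy chain, was at -4.51 ± 0.11, and acta1b, an alpha actin, at 2.21 ± 0.12. Slow muscle genes lay at -0.81 (1 of 17 above, 8 below), with the slow myosins smyhc1 and smyhc3 at -1.08 ± 0.14 and -2.43 ± 0.10. Muscle energy metabolism and glycolysis lay at -2.04, with 29 of 35 below and 0 above. Excitation-contraction coupling and neuromuscular junction lay at -0.55 with 1 of 29 above and 12 below, among them the parvalbumin pvalb2 at -6.00 ± 0.14. Presomitic mesoderm and segmentation lay at 1.37, with 18 of 24 above and 0 below. For these and all other lists, the counts against the reference were the same when adjusted over the list alone.

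Most regulators and chaperones of muscle were not called against the reference. Of 34 myogenic and somite regulators, 8 were above and 5 below at a median of log2 0.46: the myogenic factors myog and myod1 had 2.07 ± 0.13 and 1.01 ± 0.08, and the somite gene meox1 had 2.34 ± 0.08. Of 35 sarcomere chaperones and dystrophin complex genes, 9 were above and 3 below (median 0.69), with the myosin chaperone unc45b at 2.76 and the methyltransferase smyd1b at 2.70. Myoblast fusion and adhesion genes lay at 0.37 (4 of 14 above, 3 below), a median that was -0.17 under median centring, and the fusion factor mymk was at -1.09 ± 0.09 by its brightest probe but between 2.17 and 2.29 by its 3 other probes (1.39 by the mean of all). Extracellular matrix and tendon genes lay at -0.66, with 3 of 31 above and 7 below.

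The medians of the housekeeping and stress lists lay within log2 0.38 of the reference, over members on both sides of it. Cytosolic ribosomal proteins lay at a median of log2 0.38 with 4 of 94 above and 1 below, and rpl10a was at 0.08 ± 0.08. The name pattern of this list also took in S6 kinases, and the 85 members without them had a median of 0.43. Translation factors lay at 0.08, or -0.06 under median centring (18 of 79 above, 11 below), with the helicase eif4a1a at 2.80 and the elongation factor eef1a1a at -4.16. Here too the pattern drew in other kinds of gene, and the 69 members without these had a median of 0.15. Oxidative phosphorylation lay at -0.29 with 2 of 82 above and 14 below, including the muscle-type cox6a2 at -3.27. Proteasome genes lay at -0.03, or 0.08 under the processed signals, with 4 of 43 above and 0 below. Mitochondrial and cytosolic stress response genes lay at -0.15, or 0.03 with the mean of all probes (8 of 33 above, 6 below), with the immediate early gene fosab at -3.59.

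Markers of other cell types were arranged along the reference. Those of eye and lens lay at a median of log2 -4.24 (0 of 32 above, 30 below), liver at -3.41 (0 of 21 above, 20 below), pancreas at -3.40 (0 of 21 above, 19 below) and intestine at -2.73 (1 of 15 above, 12 below). The liver fatty acid binding gene fabp10a was at -5.62 ± 0.09. Neuron markers lay at -1.41 (2 of 26 above, 15 below), epidermis and periderm at -0.94 (3 of 34 above, 16 below), heart at -0.91 (0 of 18 above, 8 below) and leukocyte at -0.66 (0 of 20 above, 8 below). Cartilage and bone lay at -0.22 with 5 of 23 above and 5 below, kidney at -0.16 with 2 of 17 above and 5 below, pigment cell and neural crest at -0.01 with 4 of 18 above and 3 below, and endothelium at 0.00 with 5 of 27 above and 2 below. The medians of these last 4 lists changed sign under at least 1 other setting.

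**Figure D1:**
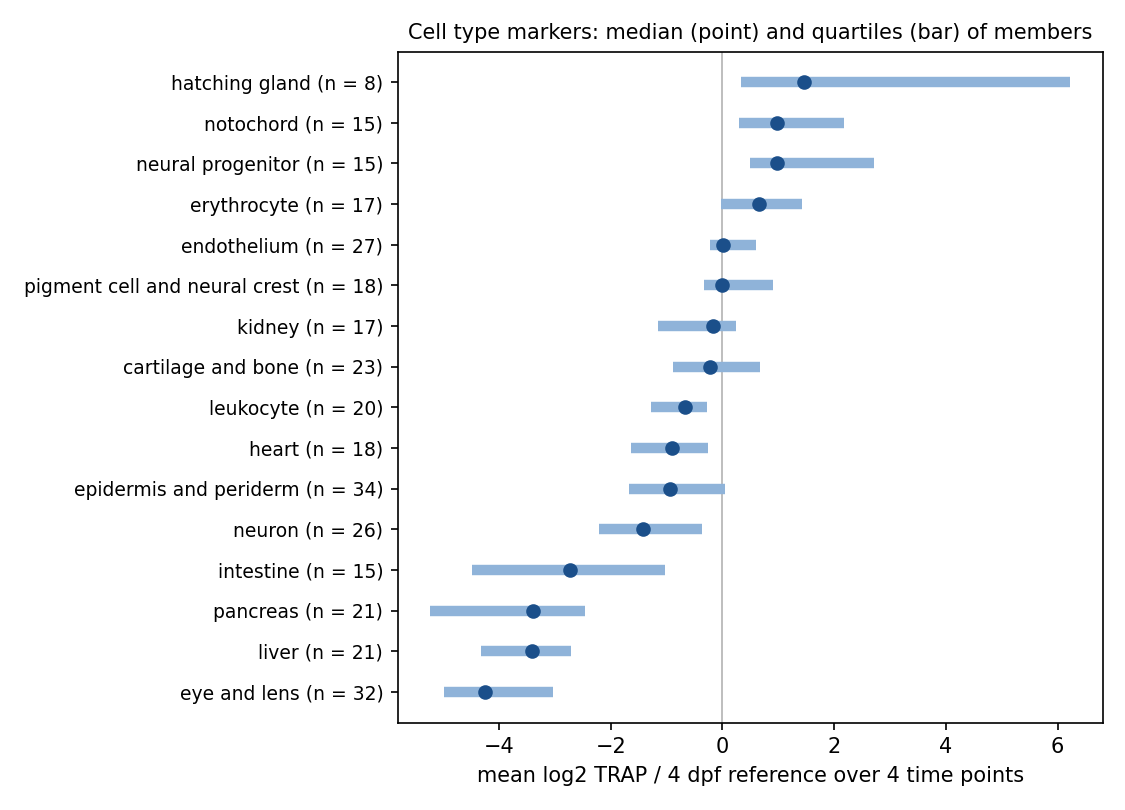
Median (point) and quartiles (bar) of the mean log2 ratio of TRAP RNA over the 4 dpf reference, on the horizontal axis, for each list of cell type markers, with the number of measured members. Hatching gland lies at the top with a median of 1.45, and eye and lens at the bottom with -4.24.

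Early embryonic cell types stood highest among the markers. Hatching gland lay at a median of log2 1.45 with 5 of 8 above the reference and 0 below, notochord at 0.98 with 7 of 15 above and 0 below, neural progenitor at 0.98 with 7 of 15 above and 1 below, and erythrocyte at 0.65 with 6 of 17 above and 1 below. The neural progenitor genes sox19a and nes had 3.86 ± 0.08 and 3.08 ± 0.10, the neural crest gene crestin had 2.97 ± 0.08 and the notochord collagen col8a1a had 4.92 ± 0.08. The pan-neuronal gene elavl3 was at 0.41 ± 0.09. Among markers outside the muscle lists, 22 of 26 for neuron and 32 of 34 for epidermis and periderm were well above background in Cy5 on all arrays, beside 25 of 32 for eye and lens.

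The linear trend over time asked how the ribosome-bound RNA changed while the muscle formed. Contractile genes rose and genes of unsegmented mesoderm fell. The fast troponin T gene tnnt3a (NM_131565; probe on chromosome 25 of Zv9, 32260194 to 32260340) rose from log2 -3.29 at 21 hpf to 2.23 at 34 hpf, a change of 5.52 (adjusted p = 0.00059), and the fast light chain mylpfb rose by 5.34. The caveolar gene cavin4a rose by 4.79, the calcium pump atp2a1 by 4.76, the calcium store protein casq1b by 4.83, the parvalbumin pvalb1 by 4.73, and the creatine kinase ckmb and the nucleotide carrier slc25a4 by 4.64 each. Also among the largest rises were tnni2a.4 and myl1, by 4.92 and 4.80. The largest rise among these named genes was in a pigment gene: gch2 (NM_131667; chromosome 12, 26618723 to 26618782), which makes a pteridine precursor, went from -0.88 through 1.89 and 3.83 to 5.27 (adjusted p = 0.00627), and the melanin gene tyrp1b rose by 5.35. The change of gch2 was 6.15 by the brightest and highest of its 4 probes, and the lowest fell short of that of tyrp1b, so its place at the top rests on the probe chosen.

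The presomitic factor msgn1 (NM_182882) fell by 5.38 on the log2 scale from 7.79, 7.04 and 5.11 at the first 3 time points, a 41.7-fold fall from 21 to 34 hpf (adjusted p = 0.00059). Its 5 probes ranged from -5.71 to -3.93. The T-box genes tbx6 and tbx16l fell by 3.73 and 3.59, and the segmentation genes ripply2 and her1 fell by 3.33 and 3.27. For her1 all reference spots were at background, so its mean was at least 4.58-fold above the reference. The notochord factor noto fell by 3.01, the homeobox gene ved fell by 3.19, the hindbrain gene egr2b by 2.85 and the keratin krt99 by 4.23. The egg envelope genes zp2.5, zp2.1 and zp2.6 fell by 3.39, 3.25 and 2.83. By limma, 1086 features rose and 467 fell of 20242, and 1292 of these 1553 calls spanned 2-fold or more between 21 and 34 hpf. In the Cy3 channel the same test called 0 features, with 1521 at an unadjusted p under 0.05. That is a share of the 20242 features above 0.05, so a weak trend in the reference channel is not excluded. Without the 34 hpf array 222 rose and 116 fell, though 1550 of the 1553 calls had the same sign. With the processed signals limma called 0, with 4396 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0925, and 1551 calls had the same sign there. The deposited table also gave 0 calls, with 4446 at an unadjusted p under 0.05.

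**Figure D2:**
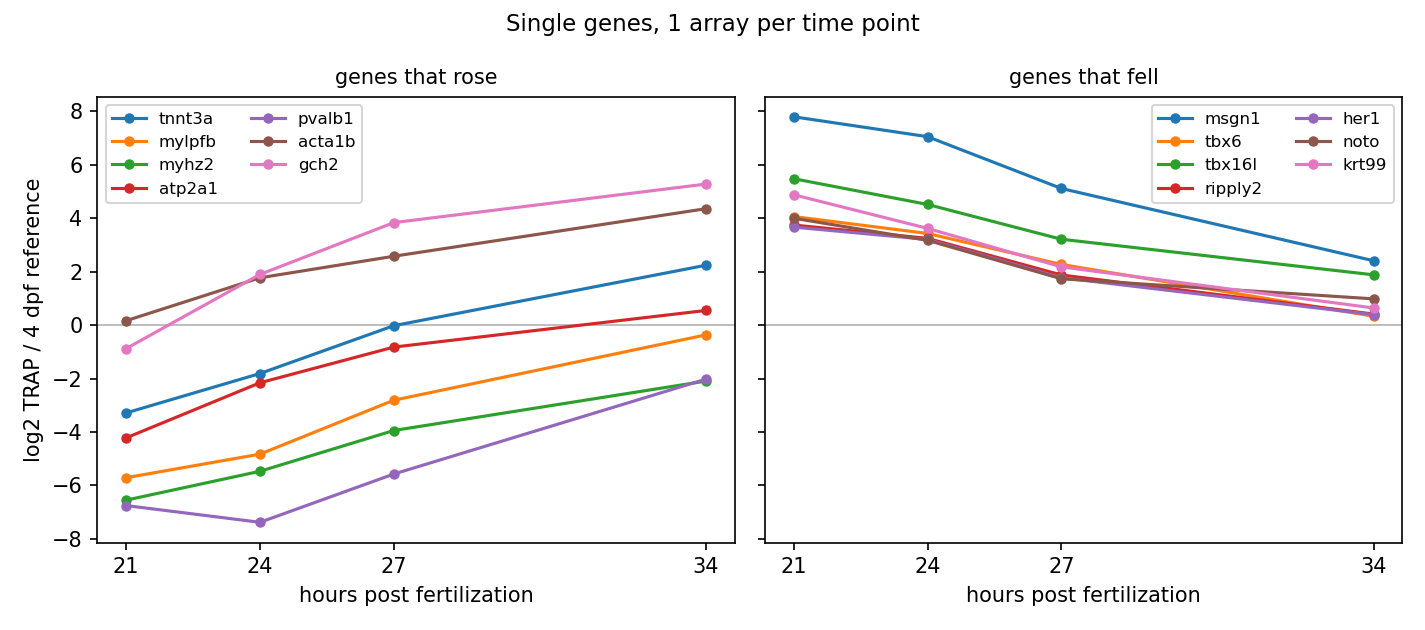
Log2 ratio of TRAP RNA over the 4 dpf reference against hours post fertilization for 7 genes that rose and 7 that fell, 1 array per time point, lines joining the arrays. msgn1 starts at 7.79 and fell by 5.38 over these hours, and tnnt3a goes from -3.29 to 2.23.

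Nearly the whole fast sarcomere list rose. Of 33 measured members 27 rose and 0 fell (30 and 0 adjusted over the list alone), and the list median went from log2 -3.41 through -3.19 and -2.22 to -0.67. The median change from 21 to 34 hpf lay above all 10000 random lists and was 2.84 with members at background set to their bound. The myosins myhz2 and myhz1.1 rose by 4.45 and 3.14, the actins acta1b and actc1b by 4.19 and 3.28, the light chain mylpfa by 3.20 and the Z-disc gene ldb3b by 4.52. Other probes of a gene often moved less than the brightest: those of acta1b ranged from 1.93 to 4.74 and those of actc1b from -0.08 to 3.28. In the slow muscle list 10 of 17 rose and 0 fell (10 and 1 adjusted over the list alone), with a median change of 1.40. The troponin tnnc1b rose by 3.07, the tropomyosin tpm2 by 2.02 and the troponin tnni1c by 1.75, while the slow myosin smyhc1 had a change of 0.90 at adjusted p = 0.306.

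Calcium handling and energy supply rose beside the sarcomere. In excitation-contraction coupling and neuromuscular junction, 21 of 29 rose and 0 fell (23 and 0 adjusted over the list alone) at a median change of log2 2.43, with pvalb2 at 4.49 and the junctophilin jph2 at 3.04. In muscle energy metabolism and glycolysis, 21 of 35 rose and 0 fell (25 and 0 adjusted over the list alone) at a median of 1.41. The glycolytic gapdh rose by 3.88, the glycogen phosphorylase pygma by 3.69 and the creatine kinase ckma by 2.13, while ampd1 had a change of -0.26. Of 35 sarcomere chaperones and dystrophin complex genes 15 rose and 0 fell (15 and 0 adjusted over the list alone), with the caveolin cav3 at 3.04, the membrane-shaping bin1b at 2.72 and the methyltransferase smyd1a at 1.89. Oxidative phosphorylation had 11 of 82 rising and 0 falling (37 and 0 adjusted over the list alone), with a median change of 0.56 and ndufa4b at 2.18. Extracellular matrix and tendon had 13 of 31 rising and 2 falling (16 and 3 adjusted over the list alone). The fibrillar collagens col1a1a and col1a1b rose by 3.30 and 3.67 and the tenascin tnn rose by 3.13, while the laminin lamb1a fell by 1.28.

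**Figure D3:**
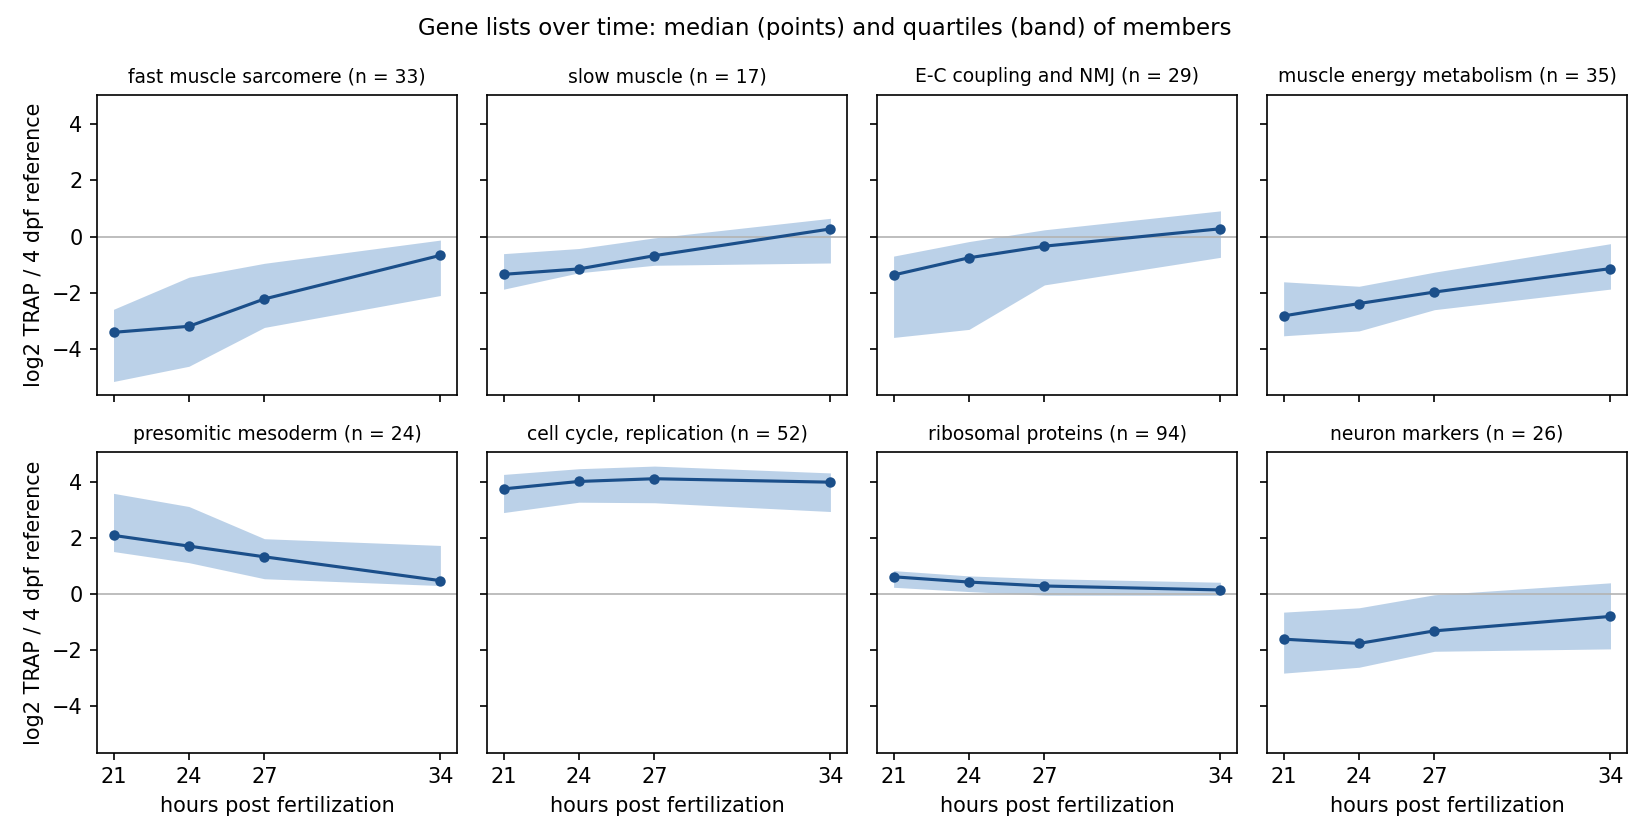
Log2 ratio of TRAP RNA over the 4 dpf reference against hours post fertilization for 8 gene lists, with the median of members as points and their quartiles as a band. The fast sarcomere median rises from -3.41 to -0.67 and the presomitic median drops from 2.09 to 0.48.

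Most measured genes of the presomitic list fell, and most myogenic regulators had no trend call. In presomitic mesoderm and segmentation 14 of 24 fell and 0 rose (15 and 1 adjusted over the list alone), with medians of log2 2.09, 1.71, 1.32 and 0.48 in order of time, a median change below all 10000 random lists. The hairy-related gene her12 had a change of -0.28 at a mean of 4.11. Of 34 myogenic and somite regulators, 7 rose and 4 fell (12 and 5 adjusted over the list alone). The early factor myf5 fell by 2.27 (adjusted p = 0.00745), myog by 1.74 and meox1 by 2.08. The repressor of slow genes sox6 rose by 1.93 and mustn1b by 3.69. For myod1 the change was 0.17 at adjusted p = 0.798, for mef2ca 1.21 at 0.0981, for pax3a -0.14 and for pax7a 0.03. In myoblast fusion and adhesion 1 of 14 rose and 0 fell (2 and 2 adjusted over the list alone), the engulfment adaptor elmo2 rising by 0.88, and mymk had -0.46.

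Proliferation and protein turnover lists had few trends. No member of the 52 cell cycle and DNA replication genes was called by limma (0 and 0 adjusted over the list alone). The median change was log2 0.04, or -0.16 in the deposited table, where the median change over intact rows was -0.17. Proteasome had 0 of 43 called (0 and 0 adjusted over the list alone). Cytosolic ribosomal proteins had 1 of 94 falling and 0 rising (0 and 0 adjusted over the list alone), the single call being rpl36, at -0.86. Their median change of -0.38 lay below all 10000 random lists, from 0.61 at 21 hpf to 0.15 at 34 hpf, and it spanned -0.70 to -0.12 over all settings. The 94 include S6 kinases, and without them the median change of the other 85 was -0.41. In the reference channel alone, scaled between arrays without loess, the median change of the 94 genes was 0.12, upward. The ratio was normalized otherwise, so how much of its drop this makes up cannot be told. Of the 79 members of the translation factor list, 69 of them without misplaced genes, 6 rose and 2 fell (7 and 7 adjusted over the list alone). The cap-binding gene eif4e2 and the poly(A)-binding gene pabpc4 rose by 1.54 and 1.51, and eef2l2 rose by 2.03. Of 33 mitochondrial and cytosolic stress response genes 2 rose and 1 fell (5 and 3 adjusted over the list alone): the endoplasmic reticulum chaperones hsp90b1 and pdia4 rose by 2.33 and 2.16 and ier2a fell by 1.23.

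Markers of several other cell types rose over the same hours. Neuron markers had 13 of 26 rising and 0 falling (18 and 0 adjusted over the list alone), with gng3 at log2 2.15 and the growth cone gene gap43 at 1.98. Epidermis and periderm had 13 of 34 rising and 0 falling (16 and 3 adjusted over the list alone), with the periderm keratin krt4 at 1.45 and the sodium pump subunit atp1b1b at 2.51. Pigment cell and neural crest had 8 of 18 rising and 0 falling (8 and 0 adjusted over the list alone), with the melanin genes dct and pmela at 3.54 and 2.91. Cartilage and bone had 7 of 23 rising and 1 falling (7 and 2 adjusted over the list alone), with epyc at 3.48 and col11a2 at 3.04. Heart had 6 of 18 rising and 0 falling (8 and 0 adjusted over the list alone), with the light chain myl7 at 2.86. Endothelium had 6 of 27 rising and 2 falling (8 and 4 adjusted over the list alone), pecam1a rising by 2.03 and lmo2 falling by 1.49. Leukocyte had 4 of 20 rising and 0 falling (5 and 1 adjusted over the list alone), with the lysozyme lyz at 2.35. Erythrocyte had 4 of 17 rising and 0 falling (11 and 1 adjusted over the list alone), and the globin hbae1.1 had a change of 3.11 at adjusted p = 0.0661.

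The remaining marker lists had between 0 and 5 rising members each. Liver had 5 of 21 rising and 1 falling (7 and 1 adjusted over the list alone) and a median change of log2 0.40, with the fibrinogen gene fga rising by 2.45 and uox falling by 1.86. Eye and lens had 3 of 32 rising and 0 falling (4 and 0 adjusted over the list alone), with the crystallin cryba1b at 2.52. Pancreas had 2 of 21 rising and 0 falling (4 and 0 adjusted over the list alone), with the somatostatin gene sst1.1 at 1.36. Neural progenitor had 2 of 15 rising and 1 falling (3 and 1 adjusted over the list alone), fabp7a rising by 2.73 and her6 falling by 1.47. Notochord had 3 of 15 rising and 4 falling (3 and 5 adjusted over the list alone), with matn3b rising by 1.98 and col8a1a falling by 2.01. Hatching gland had 1 of 8 rising, agr2, and 1 falling, klf17 (1 and 1 adjusted over the list alone). Kidney had 1 of 17 rising, slc4a4a, and 0 falling (2 and 1 adjusted over the list alone). Intestine had 0 of 15 rising and 1 falling, cdx4 (0 and 1 adjusted over the list alone).

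The difference between 34 and 21 hpf, with no test, counted 1069 features up and 480 down by 2-fold or more of 16117, against 17 up and 13 down in the reference channel. With the processed signals 2491 were up and 1494 down, and the deposited table gave 2234 and 2117, with only a small lead of rises. Genes whose TRAP signal came out of the background included the calcium store gene casq1a, at least 18.3-fold higher at 34 hpf, the actin nucleator cobl at least log2 3.53, igfn1.1 at least 3.52, the phosphofructokinase pfkma at least 3.51 and the lens channel mipa at least 3.10. Those that sank into it were the segmentation genes mespaa, with -3.03 as the bound, and mespba, with -1.90, the signalling genes wnt8-2 and admp, with -2.36 and -2.13, and the transcription factor gfi1aa, with -1.95. Such bounds rest on 1 array per time, so they carry no error.

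**Figure D4:**
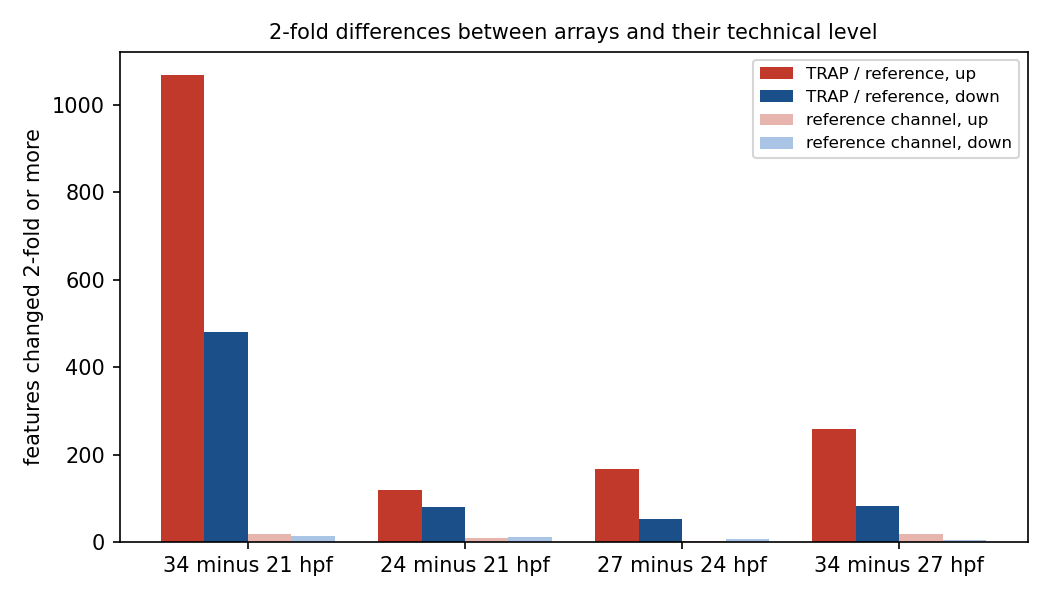
Number of features that differ 2-fold or more between the arrays of each comparison, up and down, in the ratio of TRAP RNA to reference and in the reference channel alone. From 21 to 34 hpf 1069 went up and 480 down, beside 17 and 13 in the reference channel.

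Successive intervals, compared with no test, had their own leading genes. From 21 to 24 hpf, gch2 was log2 2.77 higher, the globins hbbe1.1 and hbae1.1 2.36 and 1.97, atp2a1 2.06 and the heat shock gene hsp70 1.96. The xenobiotic enzyme gene cyp1a dropped by 2.62 and the prolyl hydroxylase gene p4ha1b dropped by 1.90, followed by egln3, gfi1aa and tnfb at -1.68, -1.61 and -1.57. This interval had 118 features up and 79 down of 16140 (8 and 12 in the reference channel). At 1.5-fold, 663 were up and 777 down. Under median centring the 2-fold counts were 409 and 25, with the processed signals 1014 and 506, and the deposited table gave 1149 and 503.

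From 24 to 27 hpf the calsequestrins casq1a and casq1b were log2 2.48 and 2.02 higher, aep1 2.13, and tnni2a.4 and tyrp1b 2.16 each. The oxygen-sensing hydroxylase egln3 dropped by 2.64, msgn1 by 1.94, the stress gene ddit4 by 1.93, the homeobox gene cdx4 by 1.77 and mespaa by 1.70. There were 166 features up and 52 down of 16116 (3 and 7 in the reference channel). With the processed signals the counts were 591 and 723, the deposited table gave 465 and 884, and median centring gave 45 and 89, so more features went down than up there.

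From 27 to 34 hpf pvalb1 and slc25a4 were log2 3.55 and 3.47 higher, hsc70 3.10, the fin ray gene and2 2.75 and aep1 2.68. In this interval msgn1 dropped by 2.70, tbx6 by 1.94, prtga by 1.80 and krt99 by 1.54, with drll.2 next. There were 259 features up and 83 down of 15877 (19 and 5 in the reference channel), with 1249 and 598 for the processed signals and 1206 and 788 for the deposited table. The intervals differ in length and were not tested against each other.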

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

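The signals in the damaged part of the 34 hpf scanner file, and all tests of explanations in this part, were chosen after the results were seen.

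Among features with an informative symbol, the deposited table still holds Cy5 values for 500 genes measured only in the damaged part. No comparison above used these 500. Taken relative to the median change of that table (-0.17), 55 of them were up and 27 down by 2-fold or more from 21 to 34 hpf. Of the 500, 30 moved by more than the largest change of any feature in the reference channel, log2 1.59. That channel was corrected with an offset and scaled between arrays, while the table was not. Passing 1.59 therefore does not show a change beyond technical noise. The 3 largest rises among named genes were ponzr3 at 4.16, the transporter gene slc22a7a at 3.81 and the cartilage matrix gene matn4 at 3.44. The largest falls were the Nodal inhibitor lft1 at -4.75, the egg nucleoplasmin npm2b at -3.39 and the matrix Gla protein gene mgp at -2.34. These are values of 1 array per time, with no test. The reference columns of the table were not used, and no explanation was tested.

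The rise of muscle genes and the fall of presomitic genes was weighed against 3 technical readings. The real order of the 4 times over the arrays gave 1553 trend calls, its reverse 554 and the highest of the rest 363. The reverse mirrors the real order but is a different fit, since the times are unevenly spaced. With an order and its reverse counted as 1 there are 12 orders, too few for a share under 0.05, so this count cannot settle chance. Over the 72 called members of 4 lists the reference channel changed by 3.39% of the change of the ratio, which argues against drift along the slide in the shared steps but not against steps of the TRAP RNA alone, such as its purification or amplification. A rising share of muscle ribosomes would lower the markers of other cell types if these were otherwise steady, and 71 of 307 rose while 11 fell. These markers may also rise with age within their own cells, which could hide such a fall, so the count cannot decide. Age, which the design names, stays open as an untested explanation, since position on the slide follows time on the 4 arrays.

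The markers of other cell types in the purified RNA were weighed next. Of 115 markers of 6 cell types grouped after their medians were seen (hatching gland, notochord, epidermis and periderm, erythrocyte, neural progenitor and endothelium), 32 were called above the reference, which bleed of the reference dye into Cy5 could not give for these. Carry-over of RNA from untagged cells cannot be told apart from tagged ribosomes in such cells: 91.3% of these markers were well above background on all arrays, but so were 83.8% of eye, liver and pancreas markers, so detection separates little, and no input RNA of the same age was hybridized. Their median lay 3.96 log2 units above that of eye, liver and pancreas markers, but the grouping fixed this outcome, so whether the older age of the reference sets which markers lie above it stays open. The markers with the brightest TRAP signal in hatching gland, epidermis and periderm, and erythrocyte were ctslb, krt4 and hbbe1.1, at 6.74, 0.05 and 0.39 over the reference.

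Fast sarcomere genes rose more than slow muscle genes, with gaps of 0.38, 0.61 and 0.86 log2 units between the medians of 33 and 17 members in the successive intervals. Compression of dim spots would remove the gap among bright members with signals free of an offset, but there it was 1.55 from 21 to 34 hpf, above that of the ratios. A fault of the 34 hpf array alone would leave none from 21 to 27 hpf, where it was 0.92. The fast list started lower, with a median ratio -2.06 relative to the slow list at 21 hpf and -0.94 at 34 hpf. A later onset of the fast programme may underlie this, but the difference between the lists had no test across replicates and their levels in the 4 dpf reference stay open.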

How the results depend on the processing

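The processed signals under the strict filter, the intensity trend in limma and the lists without doubtful members were chosen after the data were seen, and all other settings before. The deposited table could not be run against the reference, since its reference columns were not mapped. Quantile scaling of average intensity after loess left all counts as they were, so it tests nothing. No paired analysis was possible because each time point has 1 array. Leaving out each time point in turn gave 2497 to 2694 features above the reference, 3217 to 3623 below it, 222 to 1325 rising and 116 to 605 falling. The lowest trend counts are those without 34 hpf, which shortens the span of time. The causes of the shifts below were not tested except where a threshold was itself changed.

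With the processed signals, 4219 features were higher and 7055 lower than the reference, and limma called 0 rising and 0 falling (4396 at an unadjusted p under 0.05). There the changes of 2-fold or more were 2491 up and 1494 down from 21 to 34 hpf, 1014 and 506 from 21 to 24, 591 and 723 from 24 to 27, and 1249 and 598 from 27 to 34. With these signals under the strict filter, 3657 were higher and 2962 lower, limma called 843 rising and 409 falling, and the 2-fold counts were 879 down from 21 to 34, 355 up and 196 down from 21 to 24, 268 and 112 from 24 to 27, and 485 and 261 from 27 to 34. With the deposited table, limma called 0 rising and 0 falling (4446 at an unadjusted p under 0.05), with 2234 up and 2117 down from 21 to 34, 1149 and 503 from 21 to 24, 465 and 884 from 24 to 27, and 1206 and 788 from 27 to 34. From 24 to 27 hpf, falls outnumbered rises with the processed signals, the deposited table and median centring, but not with the processed signals under the strict filter.

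Median centring gave 1627 higher and 5141 lower, 409 up and 25 down from 21 to 24, and 45 up and 89 down from 24 to 27. Cy5 alone gave 940 falling, and 106 up and 24 down from 24 to 27. The strict filter gave 26 down from 24 to 27, and the mean of all probes 51 down from 21 to 24 and 107 up from 24 to 27. Without a size threshold 6798 were higher and 8532 lower. At 1.5-fold the counts up and down were 2347 and 1774 from 21 to 34, 663 and 777 from 21 to 24, 841 and 337 from 24 to 27, and 1012 and 623 from 27 to 34. At 3-fold they were 451 and 146, 18 and 8, 22 and 7, and 75 and 10.

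Among list medians, cartilage and bone over the reference turned to 0.12 under the strict filter and 0.27 with processed signals under it, where kidney turned to 0.16. Myoblast fusion and adhesion turned to -0.17 under median centring, and the change of stress response genes to -0.13 in the deposited table. That table is not scaled between arrays, and the median change over its intact rows was itself -0.17. Among genes named, mymk turned to 1.39 and tnnt1 to 1.46 over the reference with the mean of all probes. By the trend, all 99 genes named that had a call lost it with the processed signals and with the deposited table, 41 without 34 hpf, and 9 with the mean of all probes, among them elmo2, rpl36, ier2a, lmo2, pdia4 and sst1.1. Between 62.5% and 67.8% of spots were well above background in Cy5, and for dimmer ones ratios are compressed and depend on the correction.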

Other observations

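The groupings in this part were chosen after the values were seen, among genes the naming rule had picked.

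Among several named genes with their lowest value at 27 hpf, 3 are given here. The prolyl hydroxylase egln3 stood at log2 4.56, 2.88, 0.24 and 1.84 over the reference at 21, 24, 27 and 34 hpf, the collagen prolyl hydroxylase p4ha1b at 4.47, 2.57, 1.07 and 3.02, and the stress gene ddit4 at 3.10, 1.74, -0.19 and 0.63. None of the 3 passed the trend test of limma (adjusted p = 0.271, 0.639 and 0.16). In the reference channel their changes from 21 to 27 hpf were -0.02, -0.27 and -0.04, and from 27 to 34 hpf -0.10, 0.15 and 0.02. No list of related genes was tested.

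The globins hbbe1.1 and hbae1.1 rose up to 27 hpf and then levelled off. In order of time hbbe1.1 stood at log2 -2.04, 0.32, 1.71 and 1.56 and hbae1.1 at -0.64, 1.33, 2.51 and 2.48. The globin hbbe3 took a different course, with 5.73, 5.61, 6.21 and 6.26. The haem synthesis gene alas2 went from 1.45 to 2.53. Parvalbumin pvalb1, the carrier slc25a4 and hsc70 followed another course, with -7.38, -7.98 and -8.12 at 24 hpf, below their 21 hpf values, before -2.02, -2.71 and -4.02 at 34 hpf. A dip on the 24 hpf array was not particular to them. From 21 to 24 hpf the median of eye and lens markers went from -4.12 to -4.81 and that of intestine markers from -2.38 to -3.07. The fast sarcomere median rose from -3.41 to -3.19. The transcription factor osr2 rose from -4.00 to -0.84 and the ankyrin gene ank1a from -2.67 to 0.86.

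Probes of the same gene lay far apart for 3 of the named genes. For tnnt1 a pair of probes stood at -1.83 and 4.75 over the reference, for rps8b at -1.30 and 1.29, and for mymk the brightest stood at -1.09 against 2.29 for the highest of the others.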
